A study of Mus musculus with 16 samples.

How the data were processed

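Total RNA of mouse heart was profiled on 16 Affymetrix Clariom D mouse arrays, per the labels, with 4 arrays in each of 4 groups given by genotype (Ppara floxed, or Ppara deleted in cardiomyocytes) and surgery (sham, or TAC for 2 weeks). Group and replicate number came from the labels of each array, and every array was assigned to a group. The deposited table holds 1 signal per probe set and array on the log2 scale, with 72688 probe sets. That the values are log2 was read from the values themselves: they run from 0.161 to 12.4, and the natural log of the largest 16-bit scanner reading is 11.1. Per the submitters' processing notes, Affymetrix Expression Console was used; its version, the background correction, the normalization and the annotation build are not given in the sources used here. Array medians lay between 2.406 and 2.493, except for floxed sham replicate 1 at 2.637. The deposited values were taken as normalized between arrays and tested without rescaling, although this array stood apart. Quantile normalization and median-centring were run as alternatives.

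Of the probe sets, 6732 were controls and 65956 were not. The probe table gave exactly 1 gene symbol for 30604, several for 2146 and none for 33206 of the non-control probe sets. Symbols were brought up to date through gene identifiers for 827 probe sets. For a gene with several probe sets (355 genes), the one with the highest mean over the 16 arrays was used, which gave 30142 genes. Genes were tested if that mean was above the median of the means of all probe sets (2.464), which left 18341 genes. No coordinates are given because the build is not stated.

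Differences were computed with limma 3.58.1 in R 4.3.3 (lmFit on a model of 4 group means, contrasts.fit, and eBayes without trend or robust options), so that all 16 arrays shared 1 estimate of the spread. The contrasts were TAC against sham in each genotype, knockout against floxed after each surgery, and the interaction of genotype and TAC. P values were adjusted by Benjamini-Hochberg over the genes tested in a contrast, and an adjusted p under 0.05 counted as a change, with no fold threshold. Numbers after ± are SE of the limma fit for differences and SD over 4 arrays for group means. With 4 arrays per group, SE of a difference for the genes named ranged from 0.045 for Fabp3 and Sod1 to 0.381 for Nppb, the interaction aside. Sets of genes were tested with camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg over 33 lists per contrast. List scores are the mean over list members of the log2 signal centred on each gene's mean, compared between groups by exact permutation, where 0.0286 is the smallest p that 4 against 4 arrays can give. The lists came from textbook knowledge. The contrasts, filters, lists, alternatives and the rule for named genes were fixed before the data were examined; the rotation test fry, and rescaling combined with leaving out an array, were added after.

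The rule for named genes took, per contrast, Ppara, the 6 largest rises and 6 largest falls among changed genes whose groups of arrays did not overlap, up to 4 members with the smallest adjusted p of each list described, and a fixed set of genes that could be given as values whatever they did. Predicted gene models and small RNAs were left unnamed. A gene named under 2 parts of the rule counts under each.

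Alternatives were quantile normalization, median-centring, no signal filter, a filter at the 75th percentile of probe-set means (4.136), all probe sets with or without a symbol, the mean of a gene's probe sets, eBayes with trend and robust options, only the groups compared, array weights, the replicate number as a block, and leaving out each of the 16 arrays. The steps were tested on simulated data before use, in 10 runs with 200 of 18341 genes changed. For TAC against sham in floxed mice 86.6% of genes changed by 0.5 log2, 99.6% of those changed by 1 and 100% of those changed by 1.5 were recovered, with 5.31% of calls false. For the interaction the shares were 65.8%, 96.0% and 99.2%, with 5.18% of calls false. The simulated genes were independent, with the same spread in every group and no shared differences between arrays. These shares therefore need not hold for the real arrays. In simulated TAC against sham in floxed mice, with independent genes, camera called a list of 40 genes shifted by 0.2 log2 in 20 of 20 runs and an unshifted list in 0 of 20, with either correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a single gene symbol (none or several) entered no gene comparison of the report; they were tested in the fit of all probe sets above the median.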

Results

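Heart RNA was measured on 16 Clariom D mouse arrays. Per the labels, the mice were on the C57BL/6J background and carried either floxed Ppara alleles (floxed mice) or lacked Ppara in cardiomyocytes (knockout mice). Ppara encodes PPARα, a nuclear receptor that switches on genes of fatty acid use. Each genotype underwent sham surgery or transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure, and hearts were taken 2 weeks later. This gave 4 groups of 4 arrays: floxed sham, floxed TAC, knockout sham and knockout TAC. The labels call the replicates of a group biological but do not say whether an array holds RNA of 1 mouse or of several, so n counts arrays. The series compares the cardiac response to pressure load with and without cardiomyocyte Ppara. Values below are log2 differences ± SE between groups of 4 arrays, from limma with Benjamini-Hochberg adjustment over 18341 genes, and a gene was counted as changed at an adjusted p under 0.05. Array medians over all probe sets lay between 2.41 and 2.49 on the log2 scale, except for floxed sham replicate 1 at 2.64. The first principal component of the tested genes held 27.0% of the variance, the second 17.4% and the third 12.1%.

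Ppara itself was lower in every knockout array than in any floxed array. Its mean log2 signal was 6.20 ± 0.15 (SD, n = 4) in floxed sham, 5.96 ± 0.08 in floxed TAC, 5.25 ± 0.04 in knockout sham and 5.12 ± 0.09 in knockout TAC hearts. The genotype difference was -0.95 ± 0.07 after sham (adjusted p = 3.15e-07) and -0.83 ± 0.07 after TAC (adjusted p = 7.37e-06). TAC left Ppara short of the threshold in floxed mice, at -0.24 ± 0.07 (adjusted p = 0.0523), and in knockout mice, at -0.13 ± 0.07 (adjusted p = 0.319). The position of the probes relative to the deleted part of the gene is not given in the sources used here, and heart tissue also holds cells other than cardiomyocytes.

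**Figure D1:**
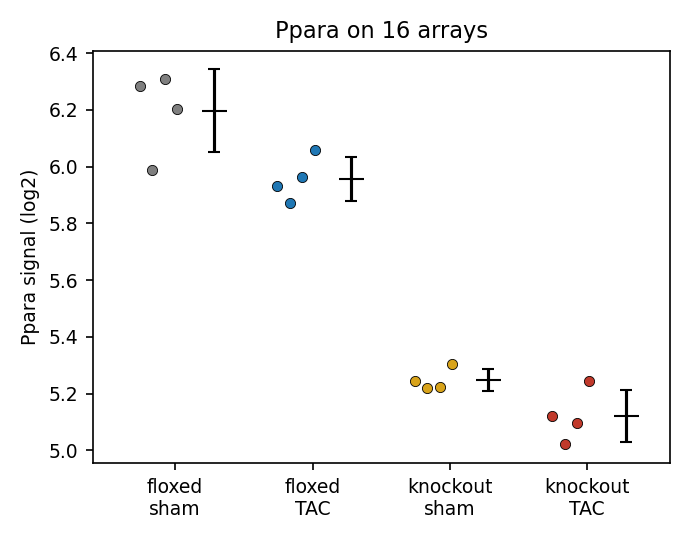
Ppara signal (vertical axis, log2) on the 16 arrays, 1 point per array, by group (horizontal axis). Horizontal ticks with bars are the mean ± SD of 4 arrays; means are 6.20, 5.96, 5.25 and 5.12 from left to right, and every knockout array lies under every floxed array.

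In floxed hearts, TAC raised 21 of 39 matrix genes and 6 of 17 hypertrophy and fetal genes and lowered 16 of 21 genes of fatty acid oxidation. None of the 33 lists passed camera with an estimated correlation (adjusted p = 0.0973 for each of these 3). The largest rises were Postn, the matricellular protein periostin, at 2.14 ± 0.24 (adjusted p = 0.000309), and Acta1, the skeletal α-actin of the fetal heart program, at 1.81 ± 0.29 (adjusted p = 0.00243). Cilp, a matrix protein, rose by 1.58 ± 0.27, Col8a1, a collagen VIII chain, by 1.16 ± 0.17, Nppa, which encodes atrial natriuretic peptide, by 1.14 ± 0.25 and Mfap5, a microfibril protein, by 1.11 ± 0.19. The largest falls were Ces1d, a carboxylesterase, at -1.33 ± 0.15 (adjusted p = 0.000355), Lgals4, a galectin, at -1.13 ± 0.11, Klhl33, a kelch-family gene, at -1.11 ± 0.13, and Fbp2, the muscle fructose-1,6-bisphosphatase, at -0.98 ± 0.10. Angpt1, the endothelial growth factor angiopoietin-1, fell by 0.95 ± 0.18 and Gpr22, a G-protein-coupled receptor, by 0.86 ± 0.15. In all, 888 of 18341 genes changed, 137 up and 751 down.

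Of 39 matrix genes, 21 rose and none fell (29 rose when adjusted over the list alone), with a median of 0.51; Col1a1 rose by 0.64 ± 0.13 and Col3a1 by 0.96 ± 0.14. Of 17 hypertrophy and fetal genes, 6 rose and none fell (13 adjusted over the list alone). Among them were Xirp2, an actin-binding repeat protein, at 0.77 ± 0.13 and Mybpc2 at 0.71 ± 0.17. Nppb, which encodes B-type natriuretic peptide, was at 1.12 ± 0.38 (adjusted p = 0.107) and Myh7, the slow myosin heavy chain, at 0.19 ± 0.10 (adjusted p = 0.315). Of 22 genes of calcium handling and ion channels, 12 fell and none rose (19 adjusted over the list alone). These included the calcium channel subunits Cacna1c at -0.42 ± 0.06 and Cacnb2 at -0.67 ± 0.10 and the potassium channel Kcnj11 at -0.45 ± 0.09. With limma's camera test these 3 lists shifted relative to other genes at the preset correlation (adjusted p = 6.44e-34, 4.78e-15 and 3.72e-13), but not with an estimated correlation (adjusted p = 0.0973 for each). Of 24 macrophage and monocyte markers 1 rose, the mannose receptor Mrc1 at 0.44 ± 0.12 (10 adjusted over the list alone). Of 8 neutrophil markers 1 rose, Lcn2 at 0.66 ± 0.16 (5 adjusted over the list alone). Camera placed both lists upwards (adjusted p = 5.48e-08 and 1.83e-05), but not with an estimated correlation (adjusted p = 0.0973 and 0.111). Of 16 fibroblast markers, 2 rose.

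Falls were also frequent in mitochondrial lists. Of 21 genes of mitochondrial fatty acid oxidation, 16 fell and none rose (21 adjusted over the list alone), with a median of -0.38. Decr1, an auxiliary enzyme of β-oxidation, fell by 0.51 ± 0.07 and Acads, the short-chain acyl-CoA dehydrogenase, by 0.47 ± 0.07. Of 39 PPARα target genes, 20 fell and none rose (26 adjusted over the list alone). Ech1 was at -0.64 ± 0.07, Retsat at -0.63 ± 0.09 and the thioesterase Acot1 at -0.79 ± 0.13. Cpt1b, the muscle carnitine palmitoyltransferase gene, was at -0.22 ± 0.07 (adjusted p = 0.0615). This list shares 27 of its tested genes with other lists. Of 21 genes of branched-chain amino acid catabolism, 16 fell (19 adjusted over the list alone), among them Bckdha at -0.64 ± 0.08, Ivd at -0.50 ± 0.07 and Mccc1 at -0.47 ± 0.06. Of 71 genes of oxidative phosphorylation 31 fell (57 adjusted over the list alone), such as Atp5e at -0.41 ± 0.06 and Ndufv1 at -0.32 ± 0.05. Of 18 tricarboxylic acid cycle genes 9 fell (16 adjusted over the list alone), such as Idh2 at -0.39 ± 0.06. At the preset correlation camera gave adjusted p = 1.61e-21 for fatty acid oxidation, 1.82e-14 for PPARα targets, 2.87e-19 for branched-chain amino acids, 4.55e-27 for oxidative phosphorylation and 3.08e-12 for the tricarboxylic acid cycle. With an estimated correlation these lists did not pass (adjusted p = 0.0973, 0.0991, 0.0973, 0.0973 and 0.16). Of 21 genes of fatty acid uptake and triglyceride turnover, 6 fell (10 adjusted over the list alone), including the transporter Slc27a1 at -0.64 ± 0.07 and the lipase Lpl at -0.32 ± 0.06 (camera adjusted p = 0.000106, and adjusted p = 0.205 with an estimated correlation). Of 23 genes of glycolysis and glucose uptake, 5 fell and 1 rose (7 and 1 adjusted over the list alone). Pfkm was at -0.36 ± 0.06, Ldhb at -0.33 ± 0.06, Hk2 at -0.33 ± 0.07 and the glucose transporter Slc2a4 at -0.34 ± 0.09 (camera adjusted p = 0.007, and adjusted p = 0.442 with an estimated correlation).

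The groups did not overlap for 820 of the 888 genes (chance gives 2.86% for a gene not selected by its p). These genes were selected by p on the same arrays, which favours groups that do not overlap, so this is no separate support. The split of directions depended on scaling: quantile normalization gave 810 genes, 273 up and 537 down, and median-centring 1006, 240 up and 766 down. A fit of these 8 arrays alone gave 362 genes, and array weights gave 532. Without floxed TAC replicate 2 the count was 431, and in that fit 15 oxidative phosphorylation genes, 5 tricarboxylic acid cycle genes and 12 PPARα targets fell. Without floxed sham replicate 1, 12 PPARα targets fell and 2 hypertrophy genes rose, while without floxed sham replicate 2 the hypertrophy count was 10 and Nppa was at 1.37. That array stood high in atrial markers (Sln at 7.16 and Myl7 at 7.36) and had the highest Nppa signal of the floxed sham arrays (10.6). Without floxed sham replicate 1 Nppa was at 0.96, short of the threshold. Of the fatty acid uptake genes, 2 fell without floxed sham replicate 1, floxed TAC replicate 1 or floxed TAC replicate 2, and 3 without floxed sham replicate 3 or after quantile normalization. No macrophage marker rose without floxed sham replicate 1, 2 or 4 or floxed TAC replicate 2 or 3 (4 rose after quantile normalization and 3 after median-centring), and 2 rose without floxed TAC replicate 4, knockout sham replicate 1 or knockout TAC replicate 3 or 4. No neutrophil marker rose without floxed sham replicate 2 or floxed TAC replicate 1, 2 or 3, and 3 rose without floxed sham replicate 4. No fibroblast marker rose without floxed sham replicate 1 or floxed TAC replicate 2, and 1 rose without floxed sham replicate 3 or 4 or floxed TAC replicate 1 or 3. The rise in 1 glycolysis gene was lost when a single array was left out, for 11 arrays: floxed sham replicate 1, 3 or 4, floxed TAC replicate 1, 2, 3 or 4, knockout sham replicate 1 or 3, or knockout TAC replicate 1 or 3. Of the 38 changed genes named for this comparison, 33 stayed past the threshold in each alternative that tested them (of these, Angpt1, Fbp2 and Klhl33 were not tested under the stricter filter); Lcn2, Mrc1, Mybpc2, Nppa and Slc2a4 did not.

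**Figure D2:**
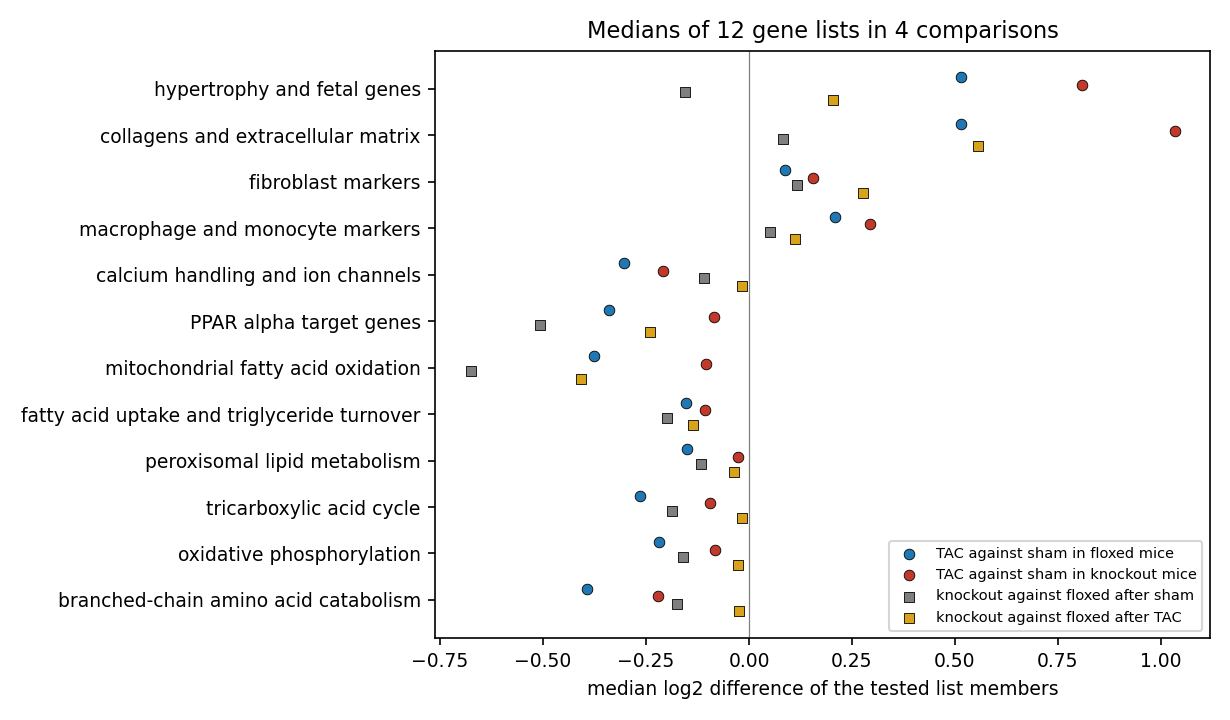
Median log2 difference (horizontal axis) of the tested members of 12 gene lists (vertical axis) in 4 comparisons, 1 symbol per list and comparison: circles for TAC against sham, squares for knockout against floxed. The matrix list lies at 0.51 and 1.03 for TAC in floxed and knockout mice, and the fatty acid oxidation list at -0.68 and -0.41 for the genotype after sham and after TAC.

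In knockout hearts, TAC raised 34 of 39 matrix genes, 16 of 17 hypertrophy and fetal genes and 10 of 24 macrophage markers. None of the 33 lists passed camera with an estimated correlation (adjusted p = 0.0785, 0.0785 and 0.152 for these 3). Postn rose by 2.74 ± 0.24 (adjusted p = 4.23e-05), Cilp by 2.58 ± 0.27 (adjusted p = 6.2e-05), Thbs4, a thrombospondin, by 2.32 ± 0.29 (adjusted p = 0.000284) and Acta1 by 2.29 ± 0.29 (adjusted p = 0.00031). Nppa rose by 1.78 ± 0.25 and Nppb by 1.78 ± 0.38. The largest falls were Ces1d at -1.21 ± 0.15, Klhl38 at -0.96 ± 0.17, the myosin light chain kinase family gene Mylk4 at -0.78 ± 0.14, Gpr22 at -0.73 ± 0.15, the potassium channel Kcnd2 at -0.70 ± 0.14 and the cardiac transcription factor Tbx5 at -0.70 ± 0.13. In all, 1067 genes changed, 795 up and 272 down.

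Of 39 matrix genes, 34 rose and none fell (35 adjusted over the list alone), with a median of 1.03: Col1a1 was at 1.17 ± 0.13, Col3a1 at 1.502 ± 0.14, Col8a1 at 1.69 ± 0.17 and the fibulin Fbln2 at 0.62 ± 0.06. Of 17 hypertrophy and fetal genes, 16 rose, also when adjusted over the list alone. These included Xirp2 at 1.24 ± 0.13, Ccn2, a matricellular growth factor, at 1.10 ± 0.16 and Myh7 at 0.43 ± 0.10. Of 24 macrophage and monocyte markers 10 rose (14 adjusted over the list alone), among them Ms4a7 at 0.62 ± 0.11, the growth factor receptor Csf1r at 0.43 ± 0.09 and lysozyme, Lyz2, at 0.47 ± 0.11. Of 14 complement genes 5 rose (7 adjusted over the list alone), with C1qb at 0.62 ± 0.14 and the inhibitor Serping1 at 0.47 ± 0.11. Of 20 interferon response genes 5 rose, with Ifi27l2a at 0.60 ± 0.13. Of 16 fibroblast markers 4 rose and 2 fell (8 and 2 adjusted over the list alone): Meox1 was at 1.63 ± 0.22, Pi16 at 0.74 ± 0.12, Islr at 0.74 ± 0.13 and Clec3b at -0.47 ± 0.09. The camera test gave adjusted p = 1.05e-49 for matrix, 2.63e-18 for hypertrophy, 2.11e-07 for macrophage, 0.000314 for complement, 0.000299 for interferon and 0.00101 for fibroblast genes. With an estimated correlation none of these passed (adjusted p = 0.0785, 0.0785, 0.152, 0.233, 0.49 and 0.49).

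Of 22 genes of calcium handling and ion channels, 10 fell and 1 rose (14 and 2 adjusted over the list alone): the calcium-binding Hrc was at -0.51 ± 0.10, Cacna1c at -0.30 ± 0.06 and calsequestrin, Casq2, at 0.33 ± 0.07. The list had a camera adjusted p = 5.15e-08, and adjusted p = 0.152 with an estimated correlation. Of 21 genes of branched-chain amino acid catabolism 7 fell (12 adjusted over the list alone), with the phosphatase Ppm1k at -0.64 ± 0.11, Bckdha at -0.48 ± 0.08 and Mccc1 at -0.35 ± 0.06. This list had a camera adjusted p = 6.51e-10, and adjusted p = 0.433 with an estimated correlation. Of 21 fatty acid oxidation genes 3 fell, namely Acaa2 at -0.46 ± 0.10, Ech1 at -0.31 ± 0.07 and Etfa at -0.27 ± 0.06 (5 adjusted over the list alone). Of 39 PPARα targets 3 fell (4 adjusted over the list alone), Acaa2 and Ech1 again and Lpl at -0.22 ± 0.06. In oxidative phosphorylation 3 of 71 fell, Ndufv1 at -0.25 ± 0.05, Ndufa5 at -0.26 ± 0.06 and Cox7a1 at -0.22 ± 0.06 (2 adjusted over the list alone), but 16 fell after quantile normalization and 13 after median-centring. The fatty acid oxidation count was 5 after quantile normalization, the PPARα target count 5 under either scaling, and the branched-chain amino acid count 11 after quantile normalization. For fatty acid oxidation, PPARα targets and oxidative phosphorylation camera gave adjusted p = 0.000347, 0.00623 and 6.15e-07, and adjusted p = 0.64 for each with an estimated correlation. Slc27a1, of the fatty acid uptake list, was at -0.56 ± 0.07.

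The groups did not overlap for 952 of the 1067 genes, which were selected by p on the same arrays (chance gives 2.86% for a gene not selected by its p). Median-centring moved the split to 840 up and 592 down of 1432, and quantile normalization to 955 up and 447 down of 1402. The count was 398 without knockout TAC replicate 2, 555 without knockout sham replicate 1, 567 without knockout TAC replicate 1, 597 without knockout sham replicate 3, 707 without knockout sham replicate 2 and 1659 without knockout TAC replicate 3. Without knockout TAC replicate 2, 32 matrix genes, 10 hypertrophy genes, 3 macrophage markers and no complement gene rose, and 3 calcium and ion channel genes fell. Macrophage markers numbered 4 without knockout TAC replicate 1 and 6 without knockout sham replicate 1 or 3, complement genes 1, 3 and 3, and falling calcium and ion channel genes 4, 4 and 5 (5 also without knockout sham replicate 2). Interferon response genes numbered 1 without knockout sham replicate 1, 3 or 4 or knockout TAC replicate 1 or 2. Without knockout TAC replicate 2 no PPARα target and no fatty acid oxidation gene fell, and without knockout sham replicate 2 these counts were 0 and 1. Oxidative phosphorylation counts were 1 without knockout sham replicate 1, 3 or 4 or knockout TAC replicate 2, and 6 without floxed sham replicate 1 or knockout TAC replicate 3. Of the fibroblast markers, 1 fell without knockout sham replicate 2 or 3 or knockout TAC replicate 1 or 2. Array weights gave 2927 genes, 1950 up and 977 down. Of the 43 changed genes named here, 32 stayed past the threshold in each alternative that tested them (of these, Ifi27l2a, Islr and Ms4a7 were not tested under the stricter filter); Acaa2, C1qb, Cox7a1, Ech1, Etfa, Lpl, Lyz2, Myh7, Ndufa5, Nppb and Serping1 did not.

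In sham-operated hearts, loss of cardiomyocyte Ppara went with lower expression of genes of fatty acid oxidation. Fbp2 fell by 1.86 ± 0.10 (adjusted p = 2.26e-08) and the acyl-CoA thioesterase Acot2 by 1.68 ± 0.16 (adjusted p = 6.64e-06). Also lower were the mitochondrial uncoupling protein gene Ucp3 at -1.47 ± 0.20, the carnitine-acylcarnitine carrier Slc25a20 at -1.47 ± 0.09, Acot1 at -1.36 ± 0.13 and Lgals4 at -1.35 ± 0.11. The largest rises were smaller: Cyp1b1, a cytochrome P450, was at 0.85 ± 0.19 (adjusted p = 0.031), Olfr1371, an olfactory receptor, at 0.47 ± 0.11. Also higher were the guidance ligand Slit3 at 0.40 ± 0.10, the GABA transaminase Abat at 0.38 ± 0.09, Prlh at 0.35 ± 0.08 and the keratin-associated Krtap5-4 at 0.34 ± 0.07. In all, 302 genes differed, 26 higher and 276 lower in knockout hearts.

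Of 21 fatty acid oxidation genes, 18 were lower and none higher (21 adjusted over the list alone), with a median of -0.68: Decr1 was at -1.29 ± 0.07, Ech1 at -1.06 ± 0.07, the electron-transfer dehydrogenase Etfdh at -0.96 ± 0.07 and Cpt1b at -0.69 ± 0.07. Of 39 PPARα targets, 25 were lower and none higher (28 lower and 1 higher adjusted over the list alone), with a median of -0.51. Pdk4, a kinase that restrains glucose oxidation, was at -0.65 ± 0.16 (adjusted p = 0.0491), and the fatty acid translocase Cd36 was at -0.18 ± 0.06 (adjusted p = 0.137). These lists had camera adjusted p = 3.36e-40 and 1.56e-32, and they also passed with an estimated correlation (adjusted p = 0.0365 for each). Of 21 genes of fatty acid uptake and triglyceride turnover, 6 were lower (12 lower and 1 higher adjusted over the list alone). These included the lipid droplet protein Plin5 at -1.19 ± 0.09, the acyltransferase Gpam at -0.90 ± 0.10, Slc27a1 at -0.40 ± 0.07 and Fabp3, the heart fatty acid binding protein, at -0.30 ± 0.045. Of 18 genes of peroxisomal lipid metabolism 6 were lower, also when adjusted over the list alone: the transporter Abcd3 was at -0.74 ± 0.06, catalase, Cat, at -0.68 ± 0.10 and Hsd17b4 at -0.46 ± 0.06. Camera gave adjusted p = 3.58e-08 and 4.93e-07 for uptake and peroxisomal genes, and adjusted p = 0.196 and 0.272 with an estimated correlation. In oxidative phosphorylation 4 of 71 genes were lower (43 adjusted over the list alone), Ndufa3 at -0.42 ± 0.07, Atp5e at -0.28 ± 0.06, Ndufb2 at -0.23 ± 0.05 and Cox6b1 at -0.21 ± 0.05 (camera adjusted p = 1.51e-17, and adjusted p = 0.272 with an estimated correlation). None of 21 cardiomyocyte structural genes passed the threshold (4 were lower adjusted over the list alone), but 21 of 21 had negative differences, with a median of -0.13. Their camera adjusted p was 0.000237, and adjusted p = 0.401 with an estimated correlation. The list score differed by -0.12 (exact permutation p = 0.0286, the smallest possible). Array medians of the positive control probe sets were also lower in knockout sham (5.809 to 5.923) than in floxed sham arrays (5.943 to 6.069). Whether these small downward shifts share a technical cause was not tested. The thiolase Acat1 was at -0.55 ± 0.09 and the superoxide dismutase Sod1 at -0.30 ± 0.045.

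None of the 39 matrix genes passed the threshold after sham, also when adjusted over the list alone, at a median of 0.08; Col1a1 was at 0.02 ± 0.13 (adjusted p = 0.942), Nppa at -0.09 ± 0.25 (adjusted p = 0.863) and Nppb at -0.29 ± 0.38 (adjusted p = 0.697). Camera nevertheless placed the matrix list upwards at the preset correlation (adjusted p = 0.000423), but not with an estimated correlation (adjusted p = 0.565). No fibroblast marker passed the threshold (2 of 16 were higher adjusted over the list alone) and no complement gene, at medians of 0.12 and 0.11. Camera placed both lists upwards (adjusted p = 0.000423 and 0.000101), but not with an estimated correlation (adjusted p = 0.292 and 0.218). None of 14 smooth muscle and pericyte markers passed the threshold (5 were lower adjusted over the list alone), at a median of -0.21 (camera adjusted p = 0.000411, and adjusted p = 0.25 with an estimated correlation). The scores differed by 0.13 for fibroblast markers (exact permutation p = 0.143), 0.13 for complement genes and -0.21 for smooth muscle markers (exact permutation p = 0.0286 for each of these 2, the smallest possible). Camera also gave adjusted p = 0.0246 for macrophage and 0.00774 for skeletal muscle markers, upwards, and 0.0453 for endothelial markers, downwards, and adjusted p = 0.467, 0.467 and 0.605 with an estimated correlation.

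Among the 302 genes, selected by p on the same arrays, 289 had groups that did not overlap (chance gives 2.86% for a gene not selected by its p). Quantile normalization gave 224 genes, 68 higher and 156 lower, and median-centring 409, 106 higher and 303 lower. The count was 190 without floxed sham replicate 1, 183 without floxed sham replicate 3, 131 without knockout sham replicate 1, 121 without knockout sham replicate 3 and 154 without knockout sham replicate 4. Of the oxidative phosphorylation genes, 1 was lower without knockout sham replicate 3, 2 without floxed sham replicate 1 or knockout sham replicate 1 or 4, 7 without floxed sham replicate 4 and 9 without floxed TAC replicate 2. Of the 31 differing genes named here, 20 stayed past the threshold in each alternative that tested them (of these, Fbp2 was not tested under the stricter filter); Abat, Atp5e, Cox6b1, Cyp1b1, Fabp3, Krtap5-4, Ndufb2, Olfr1371, Pdk4, Prlh and Slit3, among them all 6 named rises, did not.

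**Figure D3:**
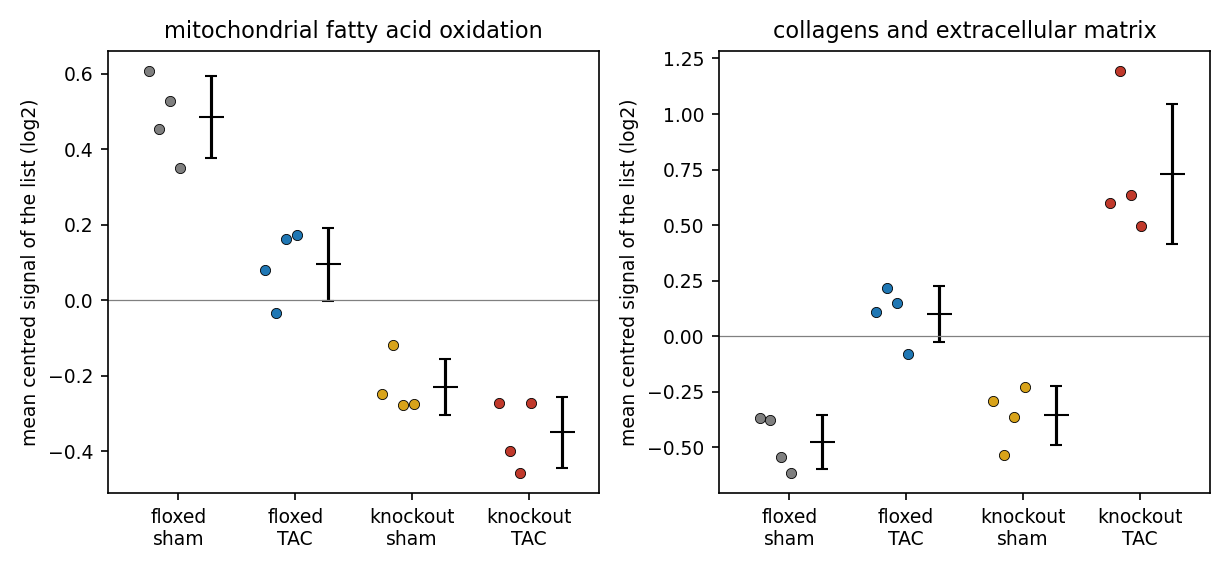
Mean centred log2 signal (vertical axis) of the tested genes of 2 lists in each array, 1 point per array, by group (horizontal axis), with ticks and bars for the mean ± SD of 4 arrays. For fatty acid oxidation genes the group means are 0.49, 0.10, -0.23 and -0.35 from left to right; for matrix genes they are -0.48, 0.10, -0.36 and 0.73, with the widest spread (SD 0.31) in knockout TAC hearts.

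After TAC, knockout hearts had higher matrix genes and lower fatty acid oxidation genes than floxed hearts. Comp, cartilage oligomeric matrix protein, was higher by 1.90 ± 0.29 (adjusted p = 0.00412), Thbs4 by 1.89 ± 0.29 (adjusted p = 0.00412), Cilp by 1.83 ± 0.27 (adjusted p = 0.00269), Angptl7 by 1.52 ± 0.27, the NADPH oxidase Nox4 by 1.21 ± 0.25 and Sfrp1, a secreted Wnt inhibitor, by 1.08 ± 0.17. The largest falls were Ucp3 at -1.32 ± 0.20, Fbp2 at -1.10 ± 0.10, Plin5 at -1.03 ± 0.09, Acot2 at -1.01 ± 0.16, Slc25a20 at -0.996 ± 0.09 and Decr1 at -0.88 ± 0.07 (adjusted p = 7.37e-06). In all, 106 genes differed, 68 higher and 38 lower in knockout hearts.

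Of 39 matrix genes, 13 were higher and none lower (30 adjusted over the list alone), with a median of 0.56. Col14a1 was at 0.91 ± 0.14 and Ltbp2, a latent TGF-β binding protein, at 1.05 ± 0.16. The collagens Col1a1 at 0.56 ± 0.13 (adjusted p = 0.0631) and Col3a1 at 0.61 ± 0.14 (adjusted p = 0.0607) fell short. Camera placed the list upwards at the preset correlation (adjusted p = 5.94e-44) and with an estimated correlation (adjusted p = 0.0448). Of 16 fibroblast markers 4 were higher (8 adjusted over the list alone), Pi16 at 0.75 ± 0.12, Dpt at 0.67 ± 0.12, Islr at 0.63 ± 0.14 and decorin, Dcn, at 0.48 ± 0.10. Of 14 complement genes 2 were higher (3 adjusted over the list alone), Serping1 at 0.65 ± 0.11 and C1ra at 0.43 ± 0.08. Camera gave adjusted p = 3.41e-09 and 2.88e-07 for fibroblast and complement genes, and adjusted p = 0.0575 and 0.0502 with an estimated correlation. None of 24 macrophage markers passed the threshold (4 were higher adjusted over the list alone), with a median of 0.11, and none of 18 endothelial markers (2 were lower adjusted over the list alone), with a median of -0.20. Camera gave these lists adjusted p = 0.000144 and 2.09e-09, and adjusted p = 0.248 and 0.19 with an estimated correlation. None of 8 neutrophil markers and none of 17 cell cycle genes passed the threshold, also when adjusted over the list alone, and 7 and 16 of them had negative differences, with medians of -0.13 and -0.23. Camera gave adjusted p = 8.81e-05 and 2.85e-05, and adjusted p = 0.19 and 0.56 with an estimated correlation. The median of the cell cycle genes was 0.02 without floxed TAC replicate 3. No hypertrophy or fetal gene passed the threshold, also when adjusted over the list alone: Nppa was at 0.56 ± 0.25 (adjusted p = 0.645), Nppb at 0.37 ± 0.38 (adjusted p = 0.999), Myh7 at 0.27 ± 0.10 (adjusted p = 0.432) and Acta1 at 0.10 ± 0.29 (adjusted p = 0.999). Camera placed that list upwards (adjusted p = 0.00287), but not with an estimated correlation (adjusted p = 0.56).

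Of 21 fatty acid oxidation genes, 12 were lower and none higher (18 adjusted over the list alone), with a median of -0.41: Acadvl, the very-long-chain acyl-CoA dehydrogenase, was at -0.72 ± 0.08, Ech1 at -0.73 ± 0.07 and Cpt1b at -0.43 ± 0.07. Of 39 PPARα targets, 14 were lower and none higher (23 adjusted over the list alone), with a median of -0.24; Acot1 was at -0.63 ± 0.13, Pdk4 at -0.56 ± 0.16 (adjusted p = 0.179) and Cd36 at -0.14 ± 0.06 (adjusted p = 0.625). These lists passed camera at the preset correlation (adjusted p = 1.15e-49 and 3.09e-44) and with an estimated correlation (adjusted p = 0.0114 for each). Of 21 genes of fatty acid uptake and triglyceride turnover, Plin5 and Slc27a1 at -0.33 ± 0.07 were lower (5 genes adjusted over the list alone; camera adjusted p = 6.22e-11, and adjusted p = 0.0502 with an estimated correlation). Of 18 genes of peroxisomal lipid metabolism, Ech1 and Abcd3 at -0.53 ± 0.06 were lower, 2 also when adjusted over the list alone (camera adjusted p = 1.77e-05, and adjusted p = 0.328 with an estimated correlation). None of the 71 oxidative phosphorylation genes passed the threshold, also when adjusted over the list alone, and 55 had negative differences, with a median of -0.03 (camera adjusted p = 0.000488, and adjusted p = 0.817 with an estimated correlation).

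Among the 106 genes, selected by p on the same arrays, 105 had groups that did not overlap (chance gives 2.86% for a gene not selected by its p). The count was 46 without floxed TAC replicate 4 (21 higher and 25 lower), 62 without floxed TAC replicate 3 (30 higher and 32 lower) and 55 without knockout TAC replicate 2. The matrix count was 8 without floxed TAC replicate 3 or 4, the fibroblast count 2 without floxed TAC replicate 3 or 4 or knockout TAC replicate 1, 2 or 4, and the complement count 1 without floxed TAC replicate 3 or 4 or knockout TAC replicate 1 or 2. The fatty acid uptake count was 1 without floxed sham replicate 4, floxed TAC replicate 1, 2, 3 or 4, knockout sham replicate 1, 3 or 4 or knockout TAC replicate 2. A fit of these 8 arrays alone gave 42 genes, 15 higher and 27 lower, so the balance of directions turned in this fit and without floxed TAC replicate 3 or 4. Array weights gave 301 genes. Of the 27 differing genes named here, 14 stayed past the threshold in each alternative that tested them (of these, Fbp2 was not tested under the stricter filter); Acot1, Angptl7, C1ra, Comp, Dcn, Islr, Ltbp2, Nox4, Serping1, Sfrp1, Slc27a1, Thbs4 and Ucp3 did not.

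The TAC effects in the 2 genotypes went together across genes. Of the 888 genes changed in floxed mice, 835 had the same sign in knockout mice, and of the 1067 changed in knockout mice, 995 had the same sign in floxed mice. In both genotypes 101 genes rose, where independent lists of these sizes would share 5.94, and 174 fell, where they would share 11.1; none went in opposite directions. Pearson's r of the log2 differences across 18341 genes was 0.576 and Spearman's rho 0.367. Genes are not independent replicates. The 2 contrasts share no arrays, but their calls use the same estimate of each gene's spread. A gene with a small spread is favoured in both lists, so the numbers for independent lists can be too low. The same holds for the genotype lists that follow. Of the 38 genes lower in knockout hearts after TAC, 37 were also among the 276 lower after sham (0.572 for independent lists), and 3 genes were higher in both (0.0964 for independent lists). Across genes the genotype effects after sham and after TAC had r = 0.364 and rho = 0.18, with r = 0.217 without knockout TAC replicate 3.

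**Figure D4:**
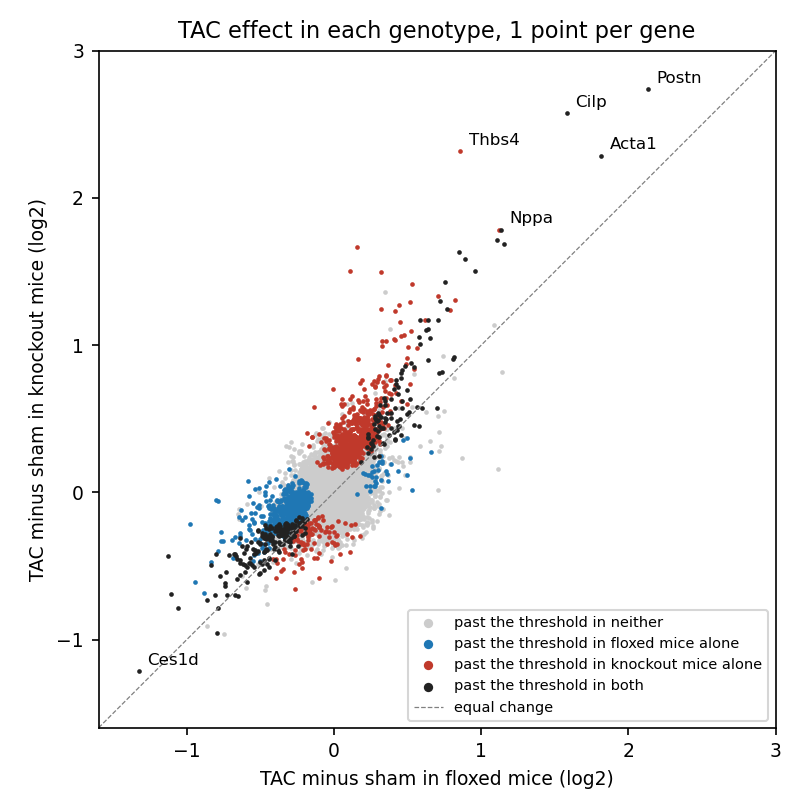
TAC minus sham difference in floxed mice (horizontal axis, log2) against that in knockout mice (vertical axis, log2), 1 point per tested gene, coloured by whether the gene passed the threshold in floxed mice, knockout mice, both or neither; the dashed line marks equal change. Postn lies at 2.14 and 2.74, Thbs4 at 0.86 and 2.32, and Ces1d at -1.33 and -1.21.

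The test of whether the TAC effect differed between genotypes called no gene with limma. The smallest adjusted p was 0.414, and 1926 genes had an unadjusted p under 0.05. The matrix genes Comp at 1.51 ± 0.41, Thbs4 at 1.46 ± 0.41 (adjusted p = 0.445 for each), Fn1 at 0.58 ± 0.17 and Tgfb3 at 0.57 ± 0.15 had larger TAC differences in knockout mice, none past the threshold. Acads at 0.45 ± 0.09, Decr1 at 0.40 ± 0.10, Acot1 at 0.73 ± 0.18, Retsat at 0.51 ± 0.12 and Me1, the malic enzyme, at 0.52 ± 0.13 were less negative in knockout mice, with adjusted p of 0.414 or 0.43. Col1a1 was at 0.53 ± 0.18, Nppa at 0.65 ± 0.35 and Nppb at 0.66 ± 0.54. As a group, the 39 matrix genes had a median interaction of 0.48 (24 genes past the threshold adjusted over the list alone), the 21 fatty acid oxidation genes 0.26 (9 genes) and the 39 PPARα targets 0.18 (13 genes). Camera gave adjusted p = 1.59e-11, 6.76e-10 and 1.24e-06 at the preset correlation and adjusted p = 0.665 for each with an estimated correlation. Fbp2, singled out after its value was seen, was at 0.77 ± 0.14 (adjusted p = 0.414), and Ppara at 0.11 ± 0.10, neither past the threshold. Fbp2 signals in knockout arrays (2.856 to 3.218) lay less than 1 log2 above the signal filter of 2.464. A signal floor may therefore contribute to the Fbp2 interaction and was not tested for this gene. The rotation test fry, which allows for correlation between genes and tests a list against no change rather than against other genes, gave adjusted p = 0.195, 0.186 and 0.195.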

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

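The splits of the arrays were planned before the data were examined; the other tests of explanations in this part were chosen after the results were seen. In each group of 4 arrays, an array was noted where its gap to the nearest other array, as a share of the group's range, exceeded Dixon's 95% critical value. Of 552 groups of values examined, 30 held such an array, where chance gives 27.6. The array noted most often was knockout TAC replicate 2, with 8 of the 30, followed by knockout sham replicate 2 with 5.

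Knockout TAC replicate 2 stood above the other knockout TAC arrays in the hypertrophy and fetal score (0.835), in the matrix genes Cilp (8.613), Thbs4 (8.043) and Tgfb3 (6.389) and in Ccn2 (7.613) and Csf1r (6.113), and below them in Cacnb2 (5.087) and Ndufb2 (4.586). Knockout TAC replicate 3 stood apart on principal component 2 (-11.24). Among floxed TAC arrays, replicate 2 stood apart in the neutrophil score (0.5716), the adipocyte score (0.1257) and Hsd17b4 (6.669), replicate 3 in the cell cycle score (0.9869), and replicate 4 in Col8a1 (4.826) and Idh2 (8.985). Among floxed sham arrays, replicate 1 stood apart in the adipocyte score (0.28), Ndufv1 (8.418) and Cd36 (10.28), replicate 2 in Lpl (10.11), and replicate 4 in Ces1d (6.594), Meox1 (4.275) and Serping1 (7.225). Among knockout sham arrays, replicate 1 stood apart in the atrial score (0.8943) and Olfr1371 (4.276), replicate 2 in the erythroid score (-0.2596), the branched-chain amino acid score (0.1636), Ldhb (10.06), Slc2a4 (7.562) and Kcnd2 (5.901), and replicate 4 in Klhl38 (5.418).

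For 14 lists the difference between genotypes in the TAC effect lay apart from that of the other genes, by camera at the preset correlation. The median differences, knockout minus floxed mice, were 0.48 for matrix, 0.321 for hypertrophy and fetal, 0.26 for fatty acid oxidation, 0.18 for PPARα target, 0.162 for tricarboxylic acid cycle, 0.148 for antioxidant, 0.145 for branched-chain amino acid, 0.143 for oxidative phosphorylation, 0.13 for glycolysis, 0.121 for peroxisomal and 0.084 for cardiomyocyte structural genes. They were -0.038 for endothelial markers, -0.195 for neutrophil markers and -0.208 for cell cycle genes. The cell cycle median was 0.029 without floxed TAC replicate 3. The endothelial median was 0.029 without knockout TAC replicate 2, 0.014 without floxed sham replicate 2 and 0.004 without floxed TAC replicate 2, so single arrays turned the sign of these 2 lists. None of the 14 passed with an estimated correlation (adjusted p = 0.703 for endothelial markers and 0.665 for each of the others), and by fry, which tests a list against no change and not against other genes, the lowest adjusted p was 0.186.

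Among 14005 tested probe sets without a single gene symbol (none or several), limma called 509 for TAC in floxed mice, 483 for TAC in knockout mice, 75 for the genotype after sham, 35 for the genotype after TAC and 0 for the interaction. What these probe sets measure was not analysed here.

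A pattern to weigh is that the genes changed by TAC were mostly falls in floxed mice (84.6%) and mostly rises in knockout mice (74.5%). Scaling as the whole cause is argued against: over quantile normalization and median-centring, with each array of a contrast left out in turn, the lowest share of falls in floxed mice was 58.2% and the lowest share of rises in knockout mice 57.9%. A part in the floxed mice may come from floxed sham replicate 1, whose array median was the highest: the share of falls was 69.9% without it and at least 83.1% without any other array of the contrast. After rescaling, leaving this array out did not lower the share (69.1% against 66.3% with quantile normalization and 77.6% against 76.1% with median-centring), as a part due to the level of this array also predicts, so that part stays open for the deposited values. The interaction, which tests the difference between genotypes, called no gene.

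Matrix genes were higher in knockout than in floxed hearts after TAC, with a median of 0.556. A single array does not account for it, since the lowest median with an array left out was 0.406, nor does scaling, since 12 matrix genes were higher after quantile normalization against 13 in the deposited values. Stronger constriction in knockout mice may contribute and stays open: the matrix score differed by 0.445 more than the hypertrophy score after TAC (exact permutation p = 0.0286, the smallest possible for 4 against 4 arrays), but by 0.172 relative to the sham arrays (exact permutation p = 0.509). A larger share of fibroblasts may contribute too and stays open: the matrix score differed by 0.338 more than the fibroblast marker score after TAC (exact permutation p = 0.0571) and by 0.345 relative to sham (exact permutation p = 0.0347). Both p relative to sham come from regrouping the genotypes within each surgery, which assumes no genotype difference in these scores after either surgery. They therefore do not test the difference relative to sham alone. Loss of Ppara in cardiomyocytes is the genotype difference that the labels name and stays among the open explanations. Any other difference between floxed and knockout mice, such as the means of deletion, cannot be told apart from it in this design.

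The genotype difference in fatty acid oxidation genes had a smaller median after TAC than after sham (median interaction 0.26), though no gene of the interaction was called. The list passed camera at the preset correlation (adjusted p = 6.76e-10). It did not pass with an estimated correlation (adjusted p = 0.665) or by fry (adjusted p = 0.186), so the difference itself is not settled. A signal floor in knockout hearts is argued against, since 100% of the list's genes lay over 1 log2 above the signal filter in knockout sham hearts (lowest mean 4.56), and a single array is too, since the lowest median interaction with an array left out was 0.224. Lower Ppara in floxed hearts after TAC may contribute and stays open: the difference was -0.24, with an adjusted p of 0.0523 in the deposited values and up to 0.0888 after rescaling.

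Other splits of the arrays gave few genes. For each contrast, 1 of the 35 splits of its 8 arrays, the real one, gave as many genes. The counts were 888 for TAC in floxed mice against a highest other of 1 and 1067 for TAC in knockout mice against 3. For the genotype they were 302 after sham against 1 and 106 after TAC against 0. This is the smallest share that 35 splits can give, so chance is made unlikely but is not excluded. Every other split mixes the real groups, which widens the estimated spread and lowers its count. The size of the gap therefore adds nothing to the rank. For the interaction, 100 groupings were compared, the real one and random regroupings of the genotypes within each surgery. All 100 gave as many genes as the real 0, with a highest other of 1. A real count of 0 fixes that outcome, so it says nothing about chance. At an unadjusted p, 4 of the 100, the real grouping among them, gave as many genes under 0.05 as the real 1926. The genotypes differed after each surgery (302 and 106 genes), so these regroupings also mix real groups and alter the spread. The 4 of 100 is therefore no p-value for the interaction alone.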

How the results depend on the processing

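Of 139 changes named, each a gene in 1 contrast, 99 stayed past the threshold under each alternative that tested them, and none changed direction. Of these 99, 8 were not tested under the stricter filter, which left them out. The interaction called 0 genes with limma under each alternative run. The lists depended most on the correlation between genes: of 83 list calls with the preset correlation, 5 passed with an estimated one and 74 after quantile normalization. With fry 44 passed, but it also tests another question, a list against no change, and was chosen after seeing the data. The stricter filter raised the correlation of the TAC effects to 0.687 and of the genotype effects to 0.489. Fitting only the groups compared gave 362 genes for TAC in floxed mice and 42 for the genotype after TAC, with fewer arrays to estimate the spread. The spread also differed between groups. The residual SD was 0.1503 in floxed sham, 0.1212 in floxed TAC, 0.1017 in knockout sham and 0.1198 in knockout TAC arrays. The fit of all 16 arrays shares 1 estimate, which is too low for floxed sham. How much of the drop comes from fewer arrays was not tested. Array weights gave 532 genes for TAC in floxed mice, 2927 for TAC in knockout mice and 301 for the genotype after TAC; the cause was not tested. With each array left out in turn, counts ranged from 431 to 1090 for TAC in floxed mice, 398 to 1659 for TAC in knockout mice, 121 to 418 for the genotype after sham and 46 to 141 for the genotype after TAC, and the correlation of the genotype effects from 0.217 to 0.471. In knockout against floxed hearts after sham, Nppa ranged from -0.266 to 0.143, Nppb from -0.681 to 0.077 and Col1a1 from -0.029 to 0.1, so that each changed sign with some array left out, and none was past the threshold; the cause was not tested. Ppara stayed past the threshold throughout. With each array left out in turn, it lay between -1.017 and -0.909 after sham and between -0.876 and -0.8 after TAC. The fit of only the groups compared was not run for the interaction, which needs all 4 groups. With the replicate number as a block, 190 genes differed between genotypes after sham, and the other counts of calls stayed within the range of leaving out arrays (787, 868, 91 and 0). The replicate numbers did not pair the arrays: of 24 same-numbered pairs 6 correlated over 0.1, the median r was 0.00992 against 0.0134 for differently numbered pairs, and 3 of 16 arrays correlated best with an array of their own number. Genes with a mean signal of 2.464 or lower were not tested, except in the fits without a filter.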

Other observations

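The single genes in this part were chosen after their values were seen, and no explanation was tested. Further fixed lists moved by camera at the preset correlation without passing with an estimated one, and not all of them are given. In floxed hearts after TAC, 17 of 17 cell cycle genes had positive differences, none past the threshold. Camera gave this list adjusted p = 1.05e-08, and adjusted p = 0.264 with an estimated correlation. Its list score was 0.9869 in floxed TAC replicate 3 and -0.0238 to 0.06706 in the other floxed TAC arrays. The score difference of 0.397 between floxed TAC and floxed sham had an exact permutation p = 0.0857, so much of it rests on 1 array. After sham, 18 of 18 tricarboxylic acid cycle genes were negative in knockout against floxed hearts, none past the threshold (10 adjusted over the list alone). Camera gave adjusted p = 6.17e-07, and adjusted p = 0.401 with an estimated correlation. In floxed hearts after TAC, 3 of 13 mitochondrial biogenesis regulators fell (7 adjusted over the list alone; 1 fell without floxed sham replicate 1 or 3 or floxed TAC replicate 2), with camera adjusted p = 0.000186, and adjusted p = 0.205 with an estimated correlation.

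Fbp2, the muscle fructose-1,6-bisphosphatase, had a log2 signal of 4.847 to 5.284 in floxed sham arrays, 3.809 to 4.226 in floxed TAC arrays and 2.856 to 3.218 in the 8 knockout arrays, so that the 3 ranges did not overlap. The knockout values lay less than 1 log2 above the signal filter of 2.464, which leaves little room for a further fall after TAC. The atrial genes Sln and Myl7 were high in 2 arrays, floxed sham replicate 2 (7.155 and 7.355) and knockout sham replicate 1 (6.608 and 7.386), and between 3.143 and 3.839 in the other 14. Cell cycle genes were highest in floxed TAC replicate 3, where Mki67 was at 6.523, Top2a at 4.336 and Ccna2 at 4.324, followed by knockout TAC replicate 1 with Mki67 at 5.195; the other 14 arrays had Mki67 between 2.813 and 4.281. The Y-linked genes Uty (5.061 to 5.407), Kdm5d (3.846 to 4.446) and Eif2s3y (4.98 to 5.361) had similar signals in all 16 arrays.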
